A study of Mus musculus with 6 samples.

How the data were processed

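RNA sequencing libraries from freshly isolated mouse splenic dendritic cells were compared between 3 libraries labelled TBK1-DKO and 3 labelled wild type (WT), with groups and replicate numbers taken from the titles and genotype labels. The labels' protocols state an age of 8 weeks and the sample characteristics an age of 10 weeks, and which holds is not known. Strain was given as C57BL/6 for all 6 samples. The abbreviation DKO is not spelled out in the sources used here, nor are the alleles, the sorting of the cells or whether each library came from a separate animal.

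The deposited values were whole-number read counts per gene symbol for 23420 genes in each of the 6 samples, neither scaled nor pooled. Per the submitters' processing notes, TopHat, TopHat2, HTSeq and DESeq2 were used with the mm10 build; versions, strand setting and annotation are not given in the sources used here. Per the labels, total RNA was extracted with Trizol and libraries were made by standard Illumina protocols, so whether reads keep strand is unknown and reads of overlapping or antisense genes were not separable. The summary rows that name no gene were kept out of library sizes and tests. They held 9.97%, 10.7% and 9.96% of all counted records in libraries TBK1-DKO 1, 2 and 3 and 8.20%, 8.67% and 8.59% in WT 1, 2 and 3. HTSeq leaves reads that align to several places or overlap several genes out of the gene counts, so levels of near-identical family members (the Ifi200, Slfn, Gbp, Klr, Ear and MHC families among them) are uncertain.

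Gene positions came from GENCODE M21 (GRCm38, the same assembly as mm10) and RefSeq. Of the 23420 symbols, 21737 matched GENCODE directly, 1272 through a synonym and 274 through RefSeq, while 137 had no position. Coordinates are 1-based.

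Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 14388 genes holding at least 99.98% of the gene reads of each library. Libraries were scaled by TMM factors (0.996 to 1.012), dispersions were estimated robustly, and the 2 groups were compared with the quasi-likelihood F test without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. Levels are counts scaled to 1000000 reads per library (CPM) as mean ± SD (n = 3 libraries per group), fold changes are log2 of TBK1-DKO over WT, and their standard errors (SE) were derived from the F statistic. Intervals are 95%. Intervals of read ratios are exact binomial (Clopper-Pearson) and cover counting error only, since reads without molecular identifiers are not independent molecules.

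Gene lists were fixed before the data were examined: 31 lists of pathways, dendritic cell subsets and other cell types, each with at least 5 tested members, plus sex-linked transcripts. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists, and again with an estimated correlation and with fry. Counts of changed members are given over all genes tested and adjusted over the list alone. Some genes, Clec9a, Irf7 and Ccl22 among them, belong to more than 1 list, so results of lists are not independent. Genes within 10 Mb of Tbk1 were compared with all others by a two-sided Fisher's exact test. Named genes followed a rule set in advance: Tbk1; the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose higher group mean reached 5 CPM; up to 4 members of each list with the smallest p; 16 preset genes of interferon signalling and dendritic cell function; up to 5 called genes nearest to Tbk1 within 10 Mb; and the sex-linked transcripts. The text prints part of the genes that rule gives.

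The tests were run on simulated counts drawn from the real means, dispersions and library sizes, with 200 genes changed, of which 197 passed the filter among 14288 genes tested. For the comparison of the groups by edgeR, 20% of genes changed by 0.3 on the log2 scale were called, 77.6% of those changed by 1.5-fold, 87.8% of those changed by 2-fold and 98.0% of those changed by 4-fold, and 4.79% of the calls were unchanged genes. With no gene changed, 2 genes and 0 lists were called. These simulated genes varied independently, which real genes do not.

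The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter and a stricter filter on low counts, the replicate number as a block, dispersions without the robust option, haemoglobin and immunoglobulin genes removed, each library left out in turn, stricter thresholds, other set tests and other windows around Tbk1. A further 3 were added after the data were seen: TBK1-DKO counts thinned at random to the mean depth of the WT libraries; per-library trends with transcript length and GC content taken out as offsets (99.0% of tested genes had both values); and a comparison without TBK1-DKO 2 and WT 1. Figures were drawn with matplotlib 3.10.9. Values of some single genes are not reported here.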

Results

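The transcriptome of splenic dendritic cells, the antigen-presenting cells of the spleen, was measured in 3 libraries labelled TBK1-DKO and 3 labelled WT. TBK1 is a kinase that relays signals from nucleic acid sensors and Toll-like receptors to interferon regulatory factors. Reads in genes numbered 47349648, 45744145 and 45018389 for TBK1-DKO 1, 2 and 3 and 31077585, 36145508 and 33740360 for WT 1, 2 and 3. The TBK1-DKO libraries were thus 1.37 times as deep on average, without overlap (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries allow).

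The groups separated along the first principal component, which held 64.1% of the variance, and single libraries stood apart along the second, with 14.9%. Library TBK1-DKO 2 differed from TBK1-DKO 1 with a chi-square of 38.1 per degree of freedom over genes, whereas TBK1-DKO 1 and 3 differed with 2.47. Among the WT libraries, the value was 13.2 for WT 1 against 2, 14.8 for WT 1 against 3 and 2.65 for WT 2 against 3. Each pair thus differed by more than sampling noise of the reads. Against the mean of the other 2 libraries of its group, TBK1-DKO 2 trended with transcript length (Spearman rho -0.556) and WT 1 with GC content (rho -0.499). The largest trends of other libraries were 0.457 with length (TBK1-DKO 3) and 0.44 with GC content (WT 3). The spread within groups thus went in part with length and GC content. The chi-square covers counting error only and does not exclude repeat preparations of 1 sample; each library was counted as a sample because the labels list it as one. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Xist, the transcript of the inactive X chromosome, had 57260 to 105720 reads in every library, and the 6 Y-linked transcripts Ddx3y, Eif2s3y, Kdm5d, Uty, Usp9y and Zfy1 had 0 reads in all 6 libraries, which allows up to 3 reads per library.

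**Figure D1:**
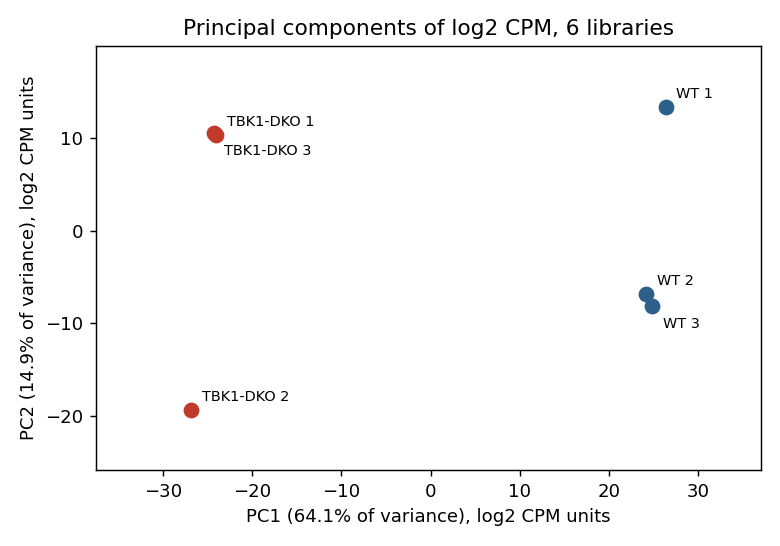
Principal components of log2 CPM of the 6 libraries, with the share of variance on each axis and 1 point per library (red, labelled TBK1-DKO; blue, labelled WT). The groups lie at opposite ends of PC1, and TBK1-DKO 2 and WT 1 lie apart from the other libraries of their groups on PC2.

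Tbk1 itself was not lower in the libraries labelled TBK1-DKO. The gene (ENSMUSG00000020115.3, chromosome 10, 121546455 to 121586787, minus strand, protein coding, 21 exons in transcript Tbk1-201) stood at 83.9, 79.2 and 83.8 CPM in TBK1-DKO 1, 2 and 3 and at 90.7, 80.8 and 83.7 CPM in WT 1, 2 and 3. The means were 82.3 ± 2.69 and 85.0 ± 5.08 CPM (SD, n = 3), a log2 fold change of -0.05 (SE 0.06, 95% interval -0.18 to 0.09; adjusted p = 0.63, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Counts over the whole gene cannot show an allele that removes part of it and leaves most of its reads, so the label was not checked by this level. The groups are therefore named by their labels throughout, and rose and fell describe the libraries labelled TBK1-DKO relative to those labelled WT. Ikbke, which encodes the closest relative of TBK1, stood at 50.8 ± 0.62 CPM against 47.9 ± 1.01 and was not called (log2 fold change 0.08, SE 0.05).

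The comparison of the labelled groups asks which transcripts differ in RNA of isolated splenic dendritic cells between TBK1-DKO and WT mice. Each library holds RNA of all cells isolated, including transcripts of other cell types. Changes in the pathway lists may therefore reflect the makeup of the cells as well as levels within dendritic cells, which was not tested. Of the genes that changed in the fixed lists, those of the cell cycle, neutrophil granules, erythroid cells, plasma cells, the interferon response and the joint list of mast cells, basophils and platelets mostly rose, and those of macrophages, NK cells, T cells, B cells, type 1 conventional dendritic cells and plasmacytoid dendritic cells mostly fell. Of 14388 genes tested, 3402 (23.6%) were called, 1978 up and 1424 down (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The balance of rises and falls depended on the model and the libraries. With length and GC offsets, added after the data were seen, 2380 were up and 2648 down. TBK1-DKO 1 and 3 against WT 2 and 3, also chosen afterwards, as the closest within groups, gave 3500 up and 3397 down. Most changes were small: the median size was 0.47 on the log2 scale, 2130 called genes changed by 1.5-fold or less, and 458 changed at least 2-fold, 289 up and 169 down. In 5909 genes (41.1%) the groups did not overlap, where chance gives 10%.

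Several single genes were nearly absent from one group. Adamdec1 (chromosome 14, 68563380 to 68582095), which encodes a secreted metalloprotease of macrophages and dendritic cells, stood at 0.19 ± 0.08 CPM in the libraries labelled TBK1-DKO and 66.2 ± 5.45 CPM in WT. Its 26 reads against 6672 correspond to a level 350 times as high in WT (interval 239 to 536). The transcript 4931429I11Rik had 8 reads against 878, a WT level 150 times as high (interval 75.6 to 348). Gm4956, Skint3, Unc5a, a netrin receptor gene, Mxra7, Eps8l1 and St6galnac1, a sialyltransferase gene, fell, with log2 fold changes between -4.02 and -2.19. In the other direction, Ifi202b (chromosome 1, 173962568 to 173982744), an interferon-inducible gene of the Ifi200 family, rose from 3.82 ± 0.30 to 36.8 ± 1.91 CPM, a log2 fold change of 3.27 (SE 0.09). Prph, which encodes the neuronal intermediate filament peripherin, rose from 2.20 ± 0.21 to 23.1 ± 2.12 CPM. Slc7a2, a cationic amino acid transporter gene, rose by 3.34 on the log2 scale (SE 0.22) and Plcd3, a phospholipase C gene, by 3.33 (SE 0.15). Itln1, Epx, the eosinophil peroxidase gene, Hr and E130309D14Rik rose by 1.96 to 2.88. These 16 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the reads of Ifi202b may be shared with its near-identical relatives.

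**Figure D2:**
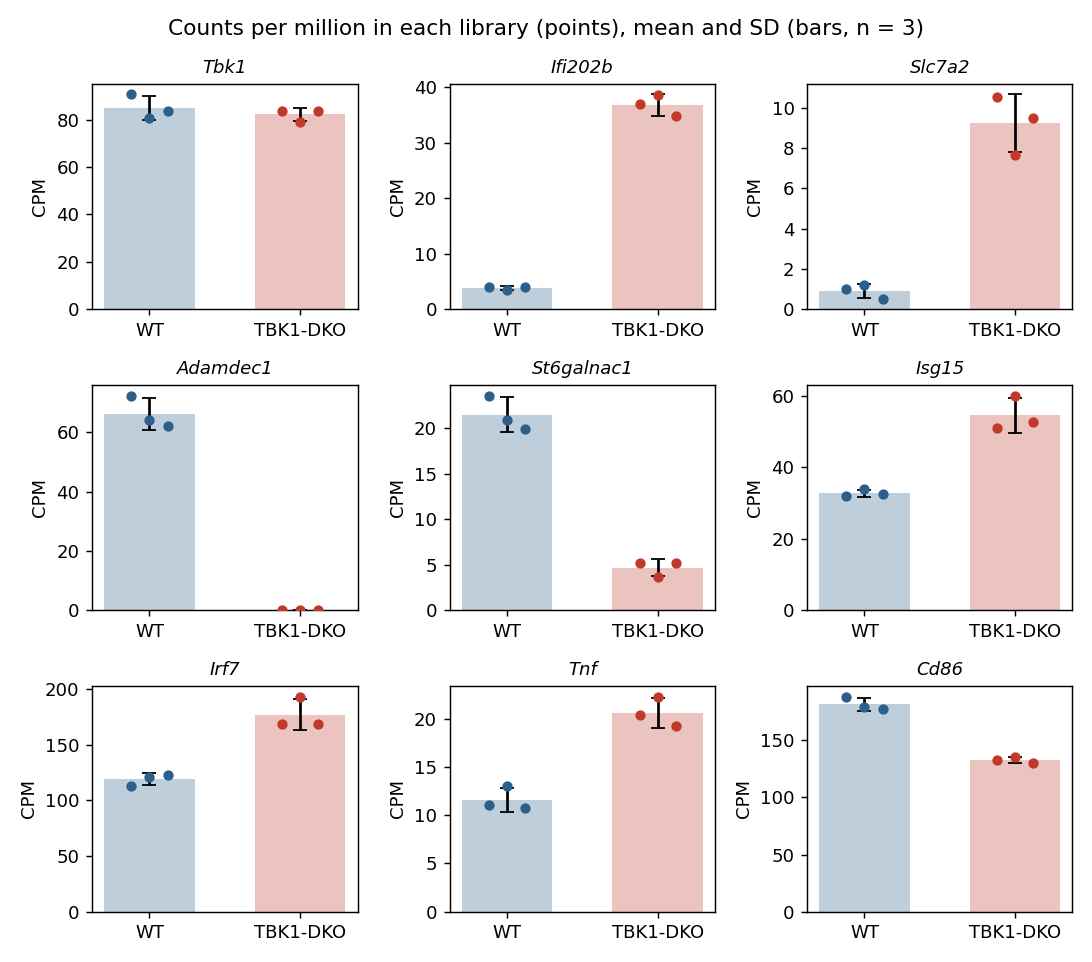
CPM of 9 named genes in each library (points), with the group mean (bar from 0) and SD (error bar, n = 3), red for libraries labelled TBK1-DKO and blue for WT. Tbk1 overlaps between the groups at 79.2 to 90.7 CPM, Adamdec1 averages 0.19 against 66.2 CPM, and Ifi202b averages 36.8 against 3.82 CPM.

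Type I interferon-stimulated genes changed in both directions, mostly upward: of 63 tested members, 32 rose, 6 fell and 25 were not called, and adjusted over the list alone 42 rose and 7 fell. Slfn8 rose from 18.9 ± 0.08 to 69.5 ± 7.52 CPM, Oas3, a sensor of double-stranded RNA, by 1.12 on the log2 scale (SE 0.07), Rsad2, which encodes the antiviral protein viperin, by 0.91 (SE 0.06), and Isg15 by 0.73 (SE 0.07). Pydc3, of the Ifi200 family, fell from 62.5 ± 0.78 to 15.8 ± 1.46 CPM. Of the members that fell, Pydc3, Pydc4 (-1.99), Mndal (-0.39) and Ifi203 (-0.30) lie between 170 and 175 Mb of chromosome 1. Large changes grouped in that stretch, and DNA of another strain there may be a source. These falls may thus reflect that locus rather than the interferon response, which was not tested. The other falls, Trim30d (-0.54) and Xaf1 (-0.34), lie outside that stretch. The list median was 0.23; camera with Benjamini-Hochberg adjustment called it up (adjusted p = 1.2e-07), and the call was lost with adjusted p = 0.064 with an estimated correlation. Ifnb1, the interferon beta gene, had too few reads to be tested. In the list of interferon receptors, JAK-STAT components and negative regulators, 5 of 21 rose, 2 fell and 14 were not called (7 and 2 adjusted over the list alone). Jak2 rose by 0.71, Usp18, a brake on interferon receptor signalling, by 0.48 and Ifnar1, a chain of the type I interferon receptor, by 0.23, while Ifngr1 fell by 0.24. The Ifnar1 call was lost without TBK1-DKO replicate 1 or 3 or WT replicate 2 or 3 (adjusted p = 0.056 to 0.11, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and the Ifngr1 call without TBK1-DKO replicate 1 (adjusted p = 0.064) or 3 (adjusted p = 0.055). Ifnar2 (-0.06) was not called. Of 36 interferon gamma-induced genes, 8 rose, 4 fell and 24 were not called (9 and 4 adjusted over the list alone). In the list of the TBK1 complex, its adaptors and upstream sensors, 4 of 23 rose, 3 fell and 16 were not called, the same counts as adjusted over the list alone. Irf7, the interferon regulatory factor, rose by 0.57 (SE 0.07) and Optn, an autophagy receptor bound by TBK1, by 0.50, while Nfkbiz fell by 0.32 and Tlr4 by 0.41, the latter a call lost without TBK1-DKO replicate 3 or WT replicate 1 (adjusted p = 0.056 and 0.083, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The last 3 lists were not called by camera with Benjamini-Hochberg adjustment (adjusted p = 0.17, 0.27 and 0.78 in the order given). Directional fry called all 3 up (adjusted p = 2.5e-04, 7.8e-04 and 0.0014 with Benjamini-Hochberg adjustment).

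Inflammatory and maturation genes also moved in both directions. In the list of dendritic cell maturation and co-stimulation, 18 of 35 rose, 5 fell and 12 were not called (20 and 5 adjusted over the list alone). Ccl22, a chemokine for regulatory T cells, rose from 20.9 ± 1.82 to 61.8 ± 4.11 CPM, and Cacnb3, Fabp5 and Cd40 rose by 0.79, 0.83 and 0.26 on the log2 scale; the Cd40 call was lost without WT replicate 2 or 3 (adjusted p = 0.08 and 0.062, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Cd86, a co-stimulatory ligand, fell by 0.45 (SE 0.05), and Cd80 (0.14), Cd274 (0.16) and Ccr7 (0.06) were not called. The list median was 0.22 (adjusted p = 3.9e-05, camera with Benjamini-Hochberg adjustment; adjusted p = 0.16 with an estimated correlation), and without WT replicate 2 the number that rose was 11 in place of 18. Of 37 NF-kB targets and inflammatory cytokines, 16 rose, 5 fell and 16 were not called (19 and 6 adjusted over the list alone). Tnf rose by 0.83 (SE 0.09) and Traf1 by 0.56, and Ptgs2 (log2 fold change -0.75) and Il18 (-0.64) fell. Il6 rose from 0.43 ± 0.06 to 0.93 ± 0.39 CPM, a call lost when any library but TBK1-DKO 3 was left out (adjusted p = 0.052 to 0.15, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Il12b (0.03) was not called. This list missed camera's threshold (adjusted p = 0.076 with Benjamini-Hochberg adjustment), while directional fry called it up (adjusted p = 0.0034 with the same adjustment). Of 24 chemokines and chemokine receptors, 6 rose, 5 fell and 13 were not called (8 and 5 adjusted over the list alone). Cxcr5 rose by 0.72, and Cxcl2 fell by 1.06. Among immediate-early and dissociation stress genes 13 of 30 fell, 1 rose and 16 were not called (13 and 2 adjusted over the list alone). Those that fell included Fosb (-1.06), Egr1 (-0.91) and Fos (-0.57). The median of this list was -0.22 (adjusted p = 4.9e-07, camera with Benjamini-Hochberg adjustment; adjusted p = 0.086 with an estimated correlation). These genes respond to handling of tissue, and they moved with the label in the same libraries as the groups above.

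Of 20 MHC class II and processing genes, 6 fell, 1 rose and 13 were not called (7 and 2 adjusted over the list alone): the cathepsin gene Ctsl fell by 0.68, Ifi30 by 0.43 and Ctsb by 0.33, H2-Eb2 rose by 0.37, and H2-Ab1, at 2222 ± 218 against 2357 ± 196 CPM, was not called. The Ctsb call was lost without WT replicate 2 or 3 (adjusted p = 0.064 and 0.052, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of 21 MHC class I genes, 3 rose, 0 fell and 18 were not called, with the same counts adjusted over the list alone; those that rose were H2-T24, Tap1 and Nlrc5. The Tap1 and Nlrc5 calls were lost when any library but TBK1-DKO 2 was left out (adjusted p = 0.055 to 0.071 and 0.058 to 0.13, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of 28 Toll-like and C-type lectin receptor genes, 9 fell, 3 rose and 16 were not called (13 and 4 adjusted over the list alone). The falls included Clec4n (log2 fold change -0.95), Tlr12 (-0.77) and Clec9a (-0.74), which is also in the list of type 1 conventional dendritic cell markers. The list median was -0.15 (adjusted p = 0.0049, camera with Benjamini-Hochberg adjustment; adjusted p = 0.2 with an estimated correlation). Among co-inhibitory and tolerogenic genes 3 of 23 rose, Lilrb4, Socs2 and Socs1, and 1 fell, Axl, an apoptotic-cell receptor gene, by 0.55, with 19 not called (6 and 5 adjusted over the list alone). The Socs1 call was lost without WT replicate 2 (adjusted p = 0.062, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Among inflammasome and cell death genes 6 of 29 rose, 4 fell and 19 were not called, the same counts as adjusted over the list alone. Casp4 rose by 1.27, Bcl2l1 by 0.62, Fas by 0.69 and Zbp1 by 0.53.

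Of 26 glycolysis and mTORC1 target genes, 8 rose, 0 fell and 18 were not called (9 and 0 adjusted over the list alone). Asns, asparagine synthetase, rose by 0.87, Hk1, hexokinase, by 0.65, Slc7a5, an amino acid transporter, by 0.64 and Slc16a1 by 0.58. Over the 26 genes the median was 0.13 (adjusted p = 0.0017, camera with Benjamini-Hochberg adjustment; adjusted p = 0.2 with an estimated correlation). Of 33 oxidative phosphorylation genes, 1 rose, Ndufb9, 1 fell, Sdha, and 31 were not called (0 and 0 adjusted over the list alone). The Ndufb9 call was lost whichever library was left out (adjusted p = 0.057 to 0.16, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and the Sdha call without TBK1-DKO replicate 1 or 3 or WT replicate 2 or 3 (adjusted p = 0.057 to 0.14). Of 45 cytosolic ribosomal protein genes edgeR, DESeq2 and limma-voom each called 0, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone by edgeR. In TBK1-DKO 1 and 3 against WT 2 and 3, chosen afterwards, camera called the ribosomal and oxidative phosphorylation lists down. Of 39 autophagy and lysosome genes, 4 rose, 3 fell and 32 were not called, and of 24 cholesterol and fatty acid synthesis genes 0 rose, 2 fell, Scd1 (-0.51) and Scd2 (-0.26), and 22 were not called; both lists gave the same counts adjusted over the list alone.

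Proliferation genes rose almost without exception, 36 of 37 called up and 1 not called (37 adjusted over the list alone). Ube2c rose from 42.6 ± 1.18 to 87.0 ± 3.55 CPM, and Aurkb, Cdc20 and Cdk1, which drive mitosis, rose by 0.88, 0.94 and 0.92 on the log2 scale. Over the 37 genes the median was 0.70 (adjusted p = 4.0e-40, camera with Benjamini-Hochberg adjustment). Neutrophil markers had the highest list median, with 15 of 17 up and 2 not called (16 adjusted over the list alone; median 1.15, adjusted p = 9.6e-35). Mpo, the myeloperoxidase gene, rose from 50.9 ± 3.66 to 197 ± 6.20 CPM, Elane, neutrophil elastase, from 16.2 ± 1.93 to 57.4 ± 4.64 CPM, Ngp from 606 ± 35.4 to 1496 ± 82.5 CPM and Ltf, lactoferrin, from 438 ± 39.5 to 1143 ± 61.1 CPM. All 15 tested erythroid markers rose (15 adjusted over the list alone; median 0.74, adjusted p = 3.0e-20), among them Slc4a1, the band 3 anion exchanger of red cells, from 861 ± 41.6 to 1589 ± 76.2 CPM. Plasma cell markers rose in 9 of 10 cases with 1 not called (9 adjusted over the list alone; median 0.69, adjusted p = 1.2e-10), including Derl3 by 1.11, Sdc1 by 0.74 and Igj, the immunoglobulin J chain, at 1522 ± 88.5 against 940 ± 67.2 CPM. Of 19 mast cell, basophil and platelet markers, 13 rose, 1 fell and 5 were not called (14 and 1 adjusted over the list alone; median 0.64, adjusted p = 2.7e-07). The basophil proteases Prss34 and Mcpt8 rose by 1.31 and 1.27 and Gata2 by 0.80. These adjusted p-values are from camera with Benjamini-Hochberg adjustment, and all 5 lists kept their calls with an estimated correlation (adjusted p = 0.041 for each).

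Markers of macrophages and lymphocytes fell more often than they rose. Of 29 macrophage and monocyte markers, 19 fell, 2 rose and 8 were not called (20 and 2 adjusted over the list alone; median -0.44). Cd163, a haemoglobin scavenger receptor of red pulp macrophages, fell from 253 ± 2.44 to 120 ± 11.7 CPM, Vcam1 from 1316 ± 30.3 to 854 ± 21.5 CPM and Timd4 by 0.70 on the log2 scale. Of 23 NK and cytotoxic lymphocyte markers, 18 fell, 0 rose and 5 were not called (18 and 0 adjusted over the list alone; median -0.48). Ifng, interferon gamma, stood at 4.04 ± 0.15 against 8.15 ± 0.54 CPM. Klre1 and Klrb1c, NK cell receptor genes, fell by 0.94 and 0.81. Of 26 T cell markers, 14 fell, 1 rose and 11 were not called (16 and 1 adjusted over the list alone; median -0.29), and those that fell included Skap1 (-0.68) and Cd3e (-0.41). Of 21 B cell markers, 11 fell, 0 rose and 10 were not called (14 and 0 adjusted over the list alone; median -0.26), led by Fcer2a, the low-affinity IgE receptor gene, at 176 ± 3.80 against 279 ± 6.38 CPM. Camera with Benjamini-Hochberg adjustment called all 4 lists down (adjusted p = 1.6e-12, 5.9e-12, 3.2e-05 and 1.1e-05). The adjusted p with an estimated correlation was 0.06 for macrophage and monocyte, 0.06 for NK, 0.063 for T cell and 0.041 for B cell markers. Of 18 stromal and endothelial markers, 5 fell, 2 rose and 11 were not called (6 and 3 adjusted over the list alone), and that list was not called (adjusted p = 0.13, camera with Benjamini-Hochberg adjustment).

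Dendritic cell subset markers fell in part. Of 19 markers of type 1 conventional dendritic cells, the cross-presenting subset, 11 fell, 3 rose and 5 were not called (12 and 3 adjusted over the list alone). Cadm1 fell from 121 ± 3.32 to 65.3 ± 3.18 CPM, Itgae by 0.82, Clec9a by 0.74 and Xcr1 by 0.48 on the log2 scale. The list median was -0.29 (adjusted p = 3.8e-05, camera with Benjamini-Hochberg adjustment; adjusted p = 0.041 with an estimated correlation). Of 21 markers of plasmacytoid dendritic cells, the main interferon producers, 13 fell, 4 rose and 4 were not called (13 and 5 adjusted over the list alone). Cox6a2 fell from 23.6 ± 0.87 to 7.85 ± 0.60 CPM and Siglech from 221 ± 15.5 to 135 ± 0.25 CPM. The list median was -0.27 (adjusted p = 3.0e-04, camera with Benjamini-Hochberg adjustment; adjusted p = 0.19 with an estimated correlation). Of 23 markers of type 2 conventional dendritic cells, 6 fell, 3 rose and 14 were not called (7 and 4 adjusted over the list alone), and the list missed the threshold (adjusted p = 0.097, camera with Benjamini-Hochberg adjustment). Directional fry called it down (adjusted p = 0.0026 with Benjamini-Hochberg adjustment).

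**Figure D3:**
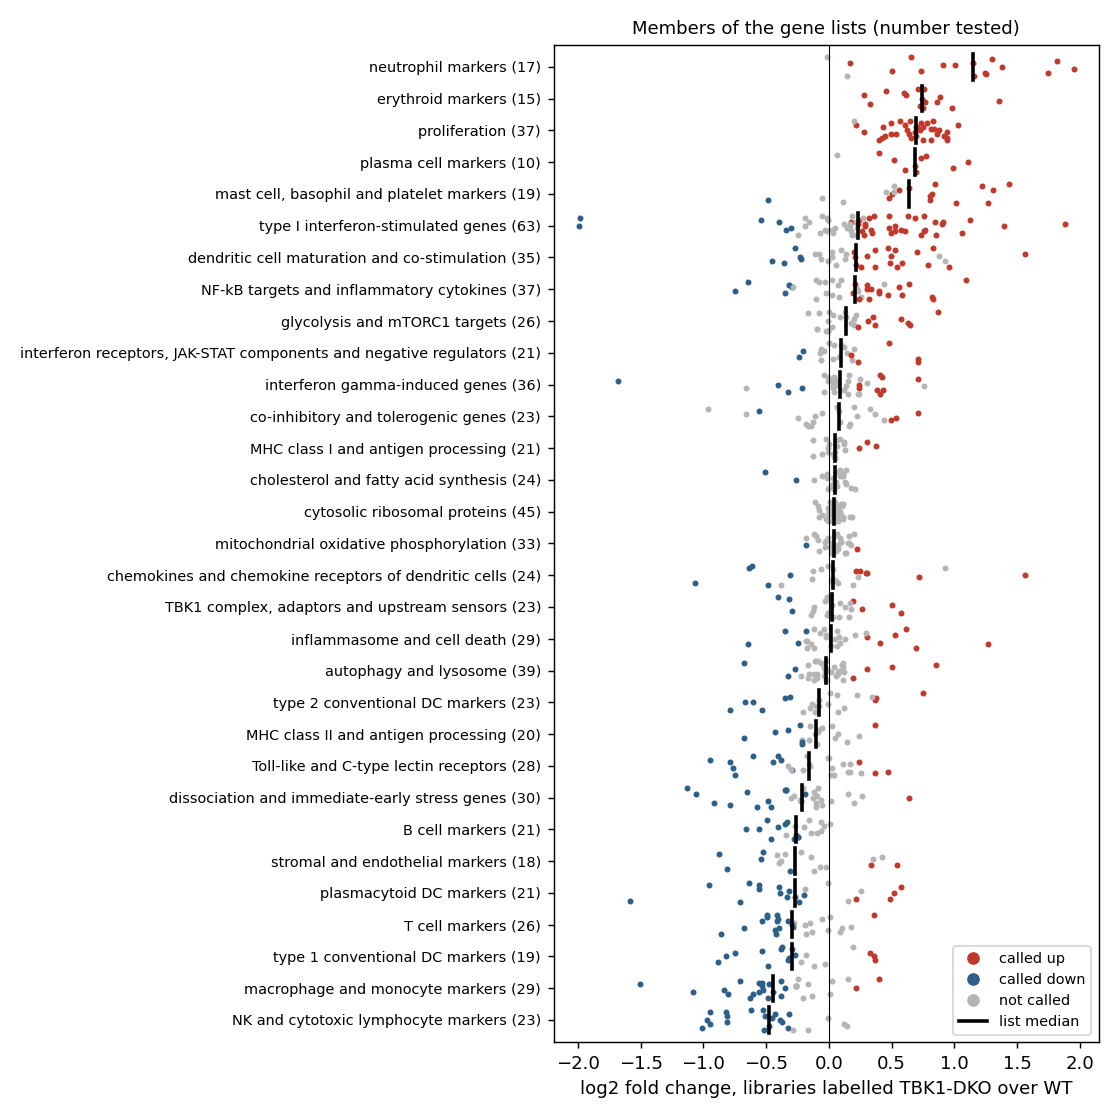
Log2 fold changes (labelled TBK1-DKO over WT) of the tested members of 31 gene lists, 1 point per gene (red, called up; blue, called down; grey, not called), with the list median as a black bar and lists ordered by it. Medians run from 1.15 for neutrophil markers to -0.48 for NK and cytotoxic lymphocyte markers.

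Camera called 16 of the 31 lists, 8 up and 8 down, and 7 of these kept their call with an estimated correlation. Fry called 22 lists in a direction and 29 in either direction. The number of preset-correlation calls did not set the labelled groups apart from other groupings. Camera called 12 to 16 lists in the other 9 splits of the 6 libraries into groups of 3. In those splits edgeR called 0 genes, with 59 to 1610 at an unadjusted p under 0.05. Each of them mixes both labels within its groups. Its list calls may thus carry part of the label difference, which also widens the spread within groups and holds gene calls down. The lists given without a set test above were not called by camera with Benjamini-Hochberg adjustment, from MHC class II (adjusted p = 0.08) to cholesterol and fatty acid synthesis (adjusted p = 0.99). Among them, directional fry called inflammasome and cell death genes up (adjusted p = 0.021 with Benjamini-Hochberg adjustment). Leaving out 1 library brought further camera calls with Benjamini-Hochberg adjustment: MHC class II down without TBK1-DKO replicate 2 (adjusted p = 0.0079) or WT replicate 1 (adjusted p = 0.025), NF-kB targets up without TBK1-DKO replicate 3 (adjusted p = 0.034) and stromal markers down without WT replicate 1 (adjusted p = 0.03).

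Whether changed genes gathered near the targeted gene was asked because DNA around a modified allele can come from another strain. Among the 139 tested genes within 10 Mb of Tbk1, 25 (18.0%) were called, against 3372 of 14197 elsewhere (23.8%), an odds ratio of 0.70 (95% interval 0.44 to 1.10; Fisher's exact test, two-sided p = 0.13). The 5 called genes nearest to Tbk1 were A130077B15Rik (log2 fold change -0.35), Hmga2 (0.45), Ppm1h (-0.40), Ifng (-1.01) and Mdm1 (0.50). The Hmga2 call was lost whichever library was left out (adjusted p = 0.055 to 0.17, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and that of A130077B15Rik without WT replicate 1 (adjusted p = 0.12) or 3 (adjusted p = 0.053). Windows of 5 Mb (odds ratio 0.805, p = 0.71) and 20 Mb (0.688, p = 0.085) also missed the threshold of Fisher's exact test. The share near Tbk1 was lower with p under the threshold of Fisher's exact test, 0.05, when DESeq2 (odds ratio 0.59, p = 0.026) or limma-voom (odds ratio 0.58, p = 0.02) made the calls, and also without TBK1-DKO replicate 2 (0.60, p = 0.012) or WT replicate 3 (0.54, p = 0.024).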

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

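All tests of explanations in this part were chosen after the result was seen. Reads that HTSeq gave to no gene, which no comparison used, were more frequent in every library labelled TBK1-DKO than in every WT library (exact permutation test, two-sided p = 0.1 for each, the smallest that 3 against 3 allow). Reads in no annotated gene made up 0.727% ± 0.011 against 0.536% ± 0.012 (SD, n = 3). Reads overlapping more than 1 gene made up 2.83% ± 0.14 against 2.32% ± 0.08. Reads aligned to more than 1 place made up 6.66% ± 0.29 against 5.63% ± 0.17.

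Marker lists of cell types moved apart, with the medians of the neutrophil, erythroid, plasma cell and mast cell, basophil and platelet lists up and those of the macrophage, NK, T and B cell lists down; the calls of the macrophage, NK, T cell and plasmacytoid dendritic cell lists were lost with an estimated correlation (adjusted p = 0.06, 0.06, 0.063 and 0.19, camera with Benjamini-Hochberg adjustment). A lower share of dendritic cells alone would raise the markers of all other types alike, but the medians of the 9 lists of other cell types spanned 1.62 on the log2 scale, more than in any of 10000 shuffles of members between lists (permutation p = 1.0e-04, the smallest that these shuffles can give). Trends with transcript length and GC content were argued against as the whole cause. Each of the 11 cell type and proliferation lists kept at least 84.3% of its median log2 fold change with length and GC offsets. After thinning, each list kept at least 83.8%. Thinning drew the same share of reads from every gene of a library, which leaves expected fold changes as they were. It therefore could not decide whether the deeper sequencing of the libraries labelled TBK1-DKO was a cause. In both settings the mean of each list's members lay more than 2 standard errors over members from 0, lowest at 2.27 for plasmacytoid dendritic cell markers after thinning. These standard errors and the shuffles treat the genes of a list as independent, which genes measured in the same libraries are not. The estimated correlation between plasmacytoid dendritic cell markers was 0.12, so both understate the spread. A different makeup of the isolated cells, with more precursors and granulocytes and fewer macrophages and lymphocytes, is a candidate explanation, and the genotype, a difference in cell isolation and a difference in library preparation stay open and untested, since each follows the same groups. Among the genes that rose, Slc4a1 reached 1589 ± 76.2 CPM and Ngp 1496 ± 82.5 CPM, and any sort or gate that would remove such cells is not given in the sources used here.

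Large changes grouped on chromosome 1 between 170 and 175 Mb, where 13 of 78 tested genes (16.7%) were called with at least a 2-fold change, 7 up and 6 down, against 3.12% elsewhere (odds ratio 6.21, 95% interval 3.11 to 11.5; Fisher's exact test, adjusted p = 5.3e-04 with Benjamini-Hochberg adjustment over 524 stretches of 5 Mb). They include Ifi202b (3.27), Itln1 (2.88), Pydc3 (-1.98) and F11r (-1.38), and the next stretch, chromosome 5 between 10 and 15 Mb, held 3 of 4 genes (adjusted p = 0.033), while 1 stretch was called when large changes were placed at random. With 1 gene kept per family, 9 of 56 genes still changed at least 2-fold (Fisher's exact test, p = 9.1e-05). The gene kept was one with a large change wherever its family had any. The large changes thus came from 9 families by symbol, but this selection could not weigh against reads shared within gene families. DNA of another strain at this stretch may be a source, as Ifi202b is known to be expressed little in C57BL/6 mice and more in some other strains; for such DNA reaching past the stretch, the 5 Mb on each side held 0 large changes among 45 genes (odds ratio 0, 95% interval up to 2.65), too few to tell. Counts hold no variants, so a strain difference cannot be told apart from a regulatory change.

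Tbk1 reads were not lower in the libraries labelled TBK1-DKO. As the reason for this, an exchange of libraries between the groups would need an allele that lowers Tbk1 reads, and low levels would then stand under the WT label; the highest library stood only 1.15 times as high as the lowest, which argues against it as that reason. With an allele that leaves the reads, Tbk1 counts say nothing on an exchange. A deletion that leaves most reads of the gene stays open: the 95% interval allows a loss of up to 11.9% of Tbk1 reads, and counts over the whole gene do not show which exons were read. An outside sample under a wrong label was not tested.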

How the results depend on the processing

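After the data were seen, 3 alternatives were chosen: thinned TBK1-DKO counts, length and GC offsets, and TBK1-DKO 1 and 3 against WT 2 and 3. The 3402 called genes (1978 up, 1424 down) became 1996 (1270 and 726) at adjusted p under 0.01 and 458 (289 and 169) with at least a 2-fold change, by construction. With length and GC offsets, falls rose to 2648 and the share of rises among calls moved from 58.1% to 47.3%. TBK1-DKO 1 and 3 against WT 2 and 3, the pairs closest to each other, gave 6897 (3500 and 3397). Keeping the closest libraries shrinks the spread within groups, which by itself raises the number of calls. None of the 3402 genes was called in the opposite direction under any other tool, scaling, filter, block, offset or set of libraries. Leaving out each library gave 2308 to 4352 calls. Called lists (16) became 7 with an estimated correlation and 29 with fry's mixed test. The odds ratio near Tbk1 (0.704) passed the threshold of Fisher's exact test with DESeq2 (0.593), limma-voom (0.580), upper-quartile factors (0.597), no filter on low counts (0.625), the replicate block (0.632) and thinned counts (0.611), missed it with windows of 5 Mb (0.805) and 20 Mb (0.688) and the other settings, and ranged from 0.535 to 0.825 without single libraries, passing without TBK1-DKO replicate 2 or WT replicate 3; the cause was not tested. Falling B cell markers (11) became 17 with offsets and 18 in the 4-library comparison, and falling immediate-early genes (13) became 21 there. Rising maturation genes (18) ranged from 11 to 16 without single libraries, lowest without WT replicate 2. The 4-library comparison reversed Xist (0.258), ribosomal proteins (-0.118) and oxidative phosphorylation (-0.057). They were called in that comparison but not with 6 libraries, and the cause was not tested. Tbk1 was not called under any setting (-0.10 to 0.02). Lists were compared by the direction and call of the set test. Of 620 alternative results of lists, 586 kept their side of the threshold, in the same direction where called. A further 23 passed it and 9 lost it, all 9 with an estimated correlation. Of 2716 values of named genes, 2634 kept their side in the same way, 24 passed and 57 lost it. A change of direction between uncalled results was not counted. Cholesterol and fatty acid synthesis, down by camera and up by fry but called by neither, was such a case. Without at least 1 single library the calls of A130077B15Rik, Cd40, Col1a1, Col3a1, Ctsb, Hmga2, Ifnar1, Ifngr1, Il6, Ndufb9, Nlrc5, Sdha, Socs1, Tap1 and Tlr4 were lost, all in the same direction (adjusted p = 0.052 to 0.17, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Same-numbered libraries correlated by 0.182, 0.149 and -0.065 in their deviations from group means. TBK1-DKO 1 and 2 each correlated best with the WT library of the same number, and TBK1-DKO 3 with WT 1 (0.121). These values do not settle whether the numbers mark pairs. With the replicate block 4086 genes and 16 lists were called. In simulation with the real library sizes and spread, 20% of changes of 0.3 on the log2 scale were called.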

Other observations

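The eosinophil list in this part was tested only after the result was seen, and the single genes named in this part were chosen after their values were seen. Of 23 markers of type 2 conventional dendritic cells, 3 rose, 6 fell and 14 were not called. The list was not called by camera (adjusted p = 0.097 with Benjamini-Hochberg adjustment) but was called down by directional fry (adjusted p = 0.0026 with the same adjustment). Esam (log2 fold change 0.75, SE 0.09) and Clec4a4 (0.37), which mark the subset with high ESAM, and Itgam (0.37) rose, and Csf1r (-0.53), Cx3cr1 (-0.30), Clec10a (-0.79) and Cd209a (-0.60) fell, as called by edgeR. Of 29 macrophage and monocyte markers 19 also fell (median -0.44; adjusted p = 1.6e-12, camera with Benjamini-Hochberg adjustment; adjusted p = 0.06 with an estimated correlation). Csf1r was the most abundant of them, at 1122 ± 17.4 against 1623 ± 74.0 CPM (SD, n = 3).

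Epx, the eosinophil peroxidase gene, was among the 8 largest rises, so more eosinophils or their precursors in the libraries labelled TBK1-DKO were considered as a hypothesis. Of 10 other eosinophil genes 7 were tested, and their median log2 fold change was -0.37: 2 rose, Prg2 (1.84) and Ear1 (2.04), 4 fell, among them Ccr3 (-0.88) and Il5ra (-0.37), and 1 was not called (camera p = 0.77; p = 0.79 with an estimated correlation). Eosinophil genes thus did not rise as a set. Since the members moved in both directions and 7 of the 10 were tested, the median does not decide the hypothesis, which stays open.

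The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The labelled split gave 3402 called genes by edgeR and was the only 1 of the 10 with as many; the highest of the other splits gave 0, with 59 to 1610 genes at an unadjusted p under 0.05. For lists called by camera, the labelled split gave 16 and the highest other split also gave 16, so that 2 of the 10 splits gave as many. The other splits mix both labels within their groups, which widens the spread there and holds gene calls down. Their list calls may carry part of the label difference. The splits therefore do not decide whether the labelled groups differ by more than chance.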
